A study of Homo sapiens with 4 samples.

How the data were processed

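The series holds RNA-seq of iMGL, microglia-like cells made from the human WTC11 induced pluripotent stem cell line, with 2 WT and 2 S1KO libraries. Per the labels' protocols, RNA was extracted with a column kit, poly-A selected and sequenced as paired reads of 150 bp. Reads were quantified with kallisto against hg38, per the submitters' processing notes; the version of kallisto and the transcript set are not given in the sources used here. The deposited values are, per the file headers, the estimated count of each transcript and its TPM, with the length and effective length, 1 file per library and no pooling. Estimated counts need not be whole, since kallisto divides a read among the transcripts it is compatible with, and TPM divides by effective length and by a total over all transcripts of the library. A library in which mitochondrial transcripts take a larger share therefore has lower TPM for every other gene.

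Transcripts were summed to genes by their identifier with GENCODE 29 (GRCh38): 169797 matched by identifier, 15521 more (mostly copies on alternate contigs) by gene symbol, and 3435 had no gene name and were left out. The unnamed transcripts took 0.323% to 0.643% of the counts of a library. INPP5D has an equal copy on an alternate contig, to which kallisto gave the same values, and both were added. Gene sums of estimated counts were rounded to whole numbers. Genes on the Y chromosome and XIST were left out of the tables of named genes. Groups came from the genotype in the labels, and each library counted as 1 replicate. In every pair of libraries at least 263 tested genes lay over 4-fold apart, so none was a copy of another. That they came from independent cultures is assumed.

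Total estimated counts per library were 21516813 to 25927881. Genes were kept by edgeR's filterByExpr (15389 of 35609), scaled by TMM (factors 1.313, 1.218, 0.653 and 0.957 in WT 1, WT 2, S1KO 1 and S1KO 2) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, in R 4.3.3) with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The total degrees of freedom were at most 6.39 per gene, and the common biological coefficient of variation was 0.29. Levels are TMM-scaled CPM without a prior count. The 95% interval of a fold change uses the SE that the test statistic implies. On simulated data for S1KO against WT with 15389 genes, 28% of genes changed 2-fold and 87% of genes changed 4-fold were called, and 13 of 142 calls were unchanged genes; DESeq2 called 32% and 87% with 16 unchanged genes, and limma on log2(TPM + 1) 5% and 64% with 1. In this simulation changes of 2-fold were mostly missed. It took each gene's spread from the fitted trend and set no library apart. The genes changed 2-fold or 4-fold were drawn from those above a minimum mean count. All lysosome list genes were also raised, by 1 on the log2 scale, and count among the calls. The simulation gave 151 calls with DESeq2, against 1160 in the data, so its shares of calls may not carry over to these libraries.

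The genes named were chosen by a rule fixed before the data were examined: INPP5D; among protein-coding genes past the threshold with mean TPM of at least 5 and with both S1KO libraries on the same side of both WT libraries, the 10 of highest and the 10 of lowest log2 fold change; up to 4 members of smallest p of each called list and of the complement, phosphoinositide and receptor adaptor lists; and a panel of 16 microglia, complement and pluripotency genes. A few genes this rule names are not reported here. Any other gene is said to be named after its value was seen, or is an example of a library that stands apart. The 27 gene lists, also fixed in advance, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom of the 4 libraries. A list that is not called there is therefore weak evidence against it, and most lists shared an adjusted p of 0.874. Principal components used the 500 most variable genes. Shares given for a single library have Wilson intervals at 95%, apart from those of single INPP5D transcripts. These intervals cover counting error only.

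The alternatives were another normalization (DESeq2's size factors), DESeq2 1.42.0 as the test, no filter, a stricter filter (at least 1 CPM in 2 libraries and mean TPM of at least 1), the replicate number as a block, each library left out, an offset for effective length, limma on log2(TPM + 1) and log2(TPM + 0.1), edgeR's legacy setting off, robust empirical Bayes, other thresholds and protein-coding genes only. Chosen after the data were seen were leaving out mitochondrial genes with their nuclear copies, using protein-coding transcripts only, and limma on TPM rescaled without mitochondrial genes. With a library left out, the group with 1 library is assumed to vary like the other group. Groups of 2 allow 3 splits of the 4 libraries, too few for a test by regrouping, and no rule for outlying samples applies to groups of this size.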

Results

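Messenger RNA was measured in microglia-like cells (iMGL) differentiated from WTC11, an established human induced pluripotent stem cell line. Unedited cells (WT) were set against cells edited to lack SHIP1 (S1KO), the inositol 5-phosphatase encoded by INPP5D, with 2 libraries per genotype. The design text states that 2 clones of each genotype were used to define microglia markers and to ask whether loss of SHIP1 impairs differentiation. The labels do not tie a replicate number to a clone, so p-values measure the spread between these libraries only. The libraries held 21516813 (WT 1), 25927881 (WT 2), 22792480 (S1KO 1) and 22334585 (S1KO 2) estimated counts. Mitochondrially encoded genes took 14.2% and 18.9% of the counts in WT 1 and WT 2, and 52.32% and 39.24% in S1KO 1 and S1KO 2. The half-width of the 95% Wilson interval of these shares was at most 0.021 percentage points, which covers counting error only. The counts left outside mitochondrial genes and their nuclear copies were 18055181 and 20539910 in WT against 9318795 and 12890924 in S1KO, so the nuclear genes were measured at lower depth in S1KO.

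**Figure D1:**
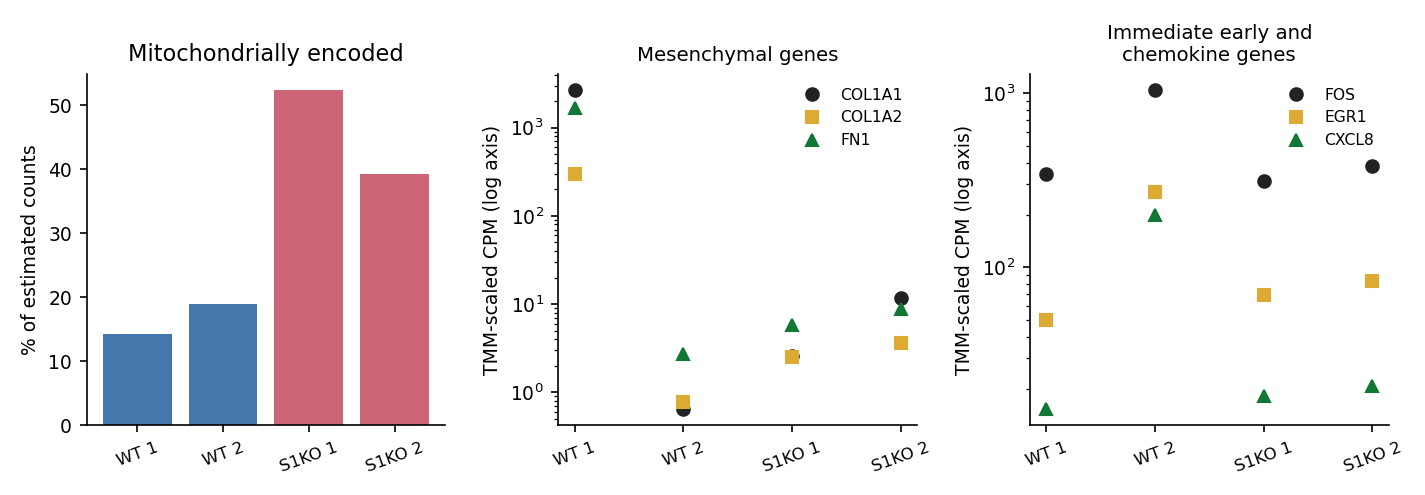
Values per library, with WT in blue and S1KO in red on the left: the percent of estimated counts on mitochondrially encoded genes, and TMM-scaled CPM on log axes for 3 mesenchymal genes and for 3 immediate early or chemokine genes. The mitochondrial share was 52.32% and 39.24% in S1KO against 14.2% and 18.9% in WT, the mesenchymal genes stood out in WT 1 (COL1A1 at 2709), and FOS, EGR1 and CXCL8 were highest in WT 2.

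The first question was whether the targeted transcript was lower in the libraries labelled S1KO. INPP5D (ENSG00000168918, chromosome 2, 233059967 to 233207903 in GRCh38, plus strand) fell by 2.16 on the log2 scale in S1KO (SE 0.21, 95% interval -2.65 to -1.66, edgeR quasi-likelihood adjusted p = 0.0185). With the effective length offset INPP5D was at -1.705 (SE 0.23, edgeR adjusted p = 0.0289). Its level was 398.2 ± 60.3 CPM (TMM-scaled counts) in WT and 89.3 ± 11.7 in S1KO (SD, n = 2 each), and both S1KO libraries lay below both WT libraries. Transcript was still present in S1KO, at 81.0 CPM in S1KO 1 and 97.6 in S1KO 2. Its direction was the same in all 17 alternatives run and 13 of them passed the threshold, with adjusted p from 6.41e-21 to 0.686. The call was lost without S1KO 1 (log2 fold change -2.04, adjusted p = 0.686) and without S1KO 2 (-2.31, adjusted p = 0.314), where a single S1KO library remained.

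The transcripts that made up the remaining INPP5D signal differed between the genotypes. Transcripts annotated as retaining an intron held 9.24% of INPP5D counts in WT 1 (95% Wilson interval 8.68 to 9.82) and 10.4% in WT 2 (9.92 to 10.94), against 18.1% in S1KO 1 (16.06 to 20.42) and 19.6% in S1KO 2 (17.95 to 21.37). The difference of the group means was 9.04 percentage points on counts and 24.2 on TPM, with no test run on 2 libraries per group. Over all protein-coding genes the retained-intron share was 10.7% and 12.3% in WT and 7.64% and 10.8% in S1KO, so the difference at INPP5D was not found over all genes. INPP5D-205, which spans 233060366 to 233141608, carried 487.4 and 656.0 estimated counts in WT and 127.8 and 255.5 in S1KO, not scaled for depth. Its share of INPP5D counts was 4.9% and 4.75% in WT and 10.6% and 12.3% in S1KO. INPP5D-210, a 439-nt retained-intron transcript at 233170021 to 233171249, had 37.0 and 37.1 counts in WT and 38.4 and 82.3 in S1KO, also not scaled for depth. It held 0.37% and 0.27% of INPP5D counts in WT against 3.19% and 3.96% in S1KO. Of INPP5D TPM it held 4.39% and 2.98% against 27.7% and 31.6%, so the TPM excess lay mainly in this short transcript. INPP5D-213, also of this type, went from 11.9% and 16.5% of TPM in WT to 9.27% and 6.47% in S1KO. The position of the edit is not given in the sources used here, so none of these transcripts could be placed relative to it.

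**Figure D2:**
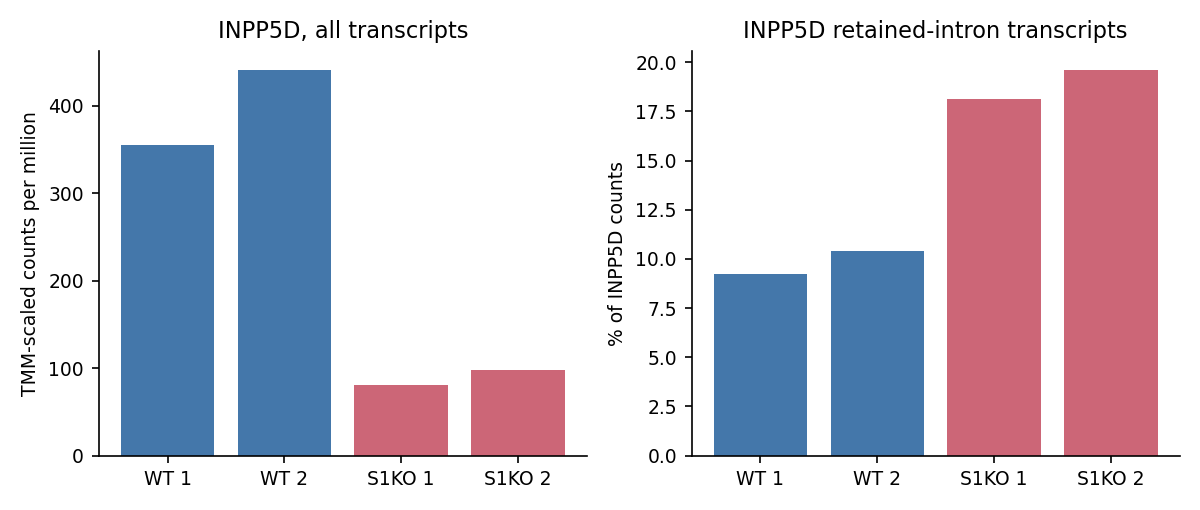
INPP5D in each library, with WT in blue and S1KO in red: TMM-scaled CPM over all transcripts (left) and the percent of INPP5D counts on retained-intron transcripts (right). Each bar is 1 library; S1KO libraries stood at 81.0 and 97.6 CPM and at 18.1% and 19.6% retained intron.

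Across the transcriptome, the genes of highest fold change in S1KO included a sterol hydroxylase, a proton pump subunit and a kinase, and those of lowest fold change included a chemokine, a pair of desaturases and a microglial receptor. CYP27A1, the mitochondrial sterol 27-hydroxylase, rose 26.0-fold (log2 fold change 4.70 ± 0.31 SE, adjusted p = 0.0174), from 1.32 and 1.25 CPM in WT to 40.4 and 26.6 in S1KO. ATP6V0D2, a subunit of the vacuolar proton pump, rose 15.3-fold (3.93 ± 0.31 SE, adjusted p = 0.0174), and MATK, a kinase of the CSK family, rose 14.8-fold (3.88 ± 0.34 SE, adjusted p = 0.0174). These rises depended on the scale: on log2(TPM + 1) they were 2.87 for CYP27A1, 2.18 for ATP6V0D2 and 1.53 for MATK, and with mitochondrial genes left out of the TPM total, chosen after the data were seen, 4.12, 3.34 and 2.63, while the effective length offset gave 4.81, 3.61 and 2.86. Each passed the threshold in 13 of its 17 alternatives. CCL2, a monocyte chemoattractant, fell by 3.18 on the log2 scale (SE 0.28, adjusted p = 0.0174), from 20.3 and 26.9 to 2.29 and 2.87 CPM. SCD and FADS2, both fatty acid desaturases, fell by 1.41 (SE 0.21, adjusted p = 0.0485) and 1.63 (SE 0.23, adjusted p = 0.0444), and passed in 11 and 12 of their 17 alternatives.

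The other named genes higher in S1KO were ADAMTSL3 (log2 fold change 4.32), FAM92B (3.24), KIAA1328 (2.70), NMNAT3, an enzyme of NAD synthesis (2.66), OR4F17 (2.87) and NBPF19 (2.49). The last 2 belong to families of near-identical genes between which pseudoalignment can divide reads, so their values are uncertain. The other named genes lower in S1KO were SERPINA1, a protease inhibitor (-2.17), IGFBP4, which binds insulin-like growth factors (-2.11), SPTBN1, a spectrin (-1.85), CPVL, a carboxypeptidase-like protein (-1.69), ADGRG1, an adhesion receptor (-1.49), and P2RY12, the ADP receptor of microglia (-1.45). Adjusted p for these 12 genes ran from 0.0174 to 0.0485, and in each both S1KO libraries lay on the same side of both WT libraries. They passed in 10 (P2RY12) to 13 of their 16 or 17 alternatives.

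**Figure D3:**
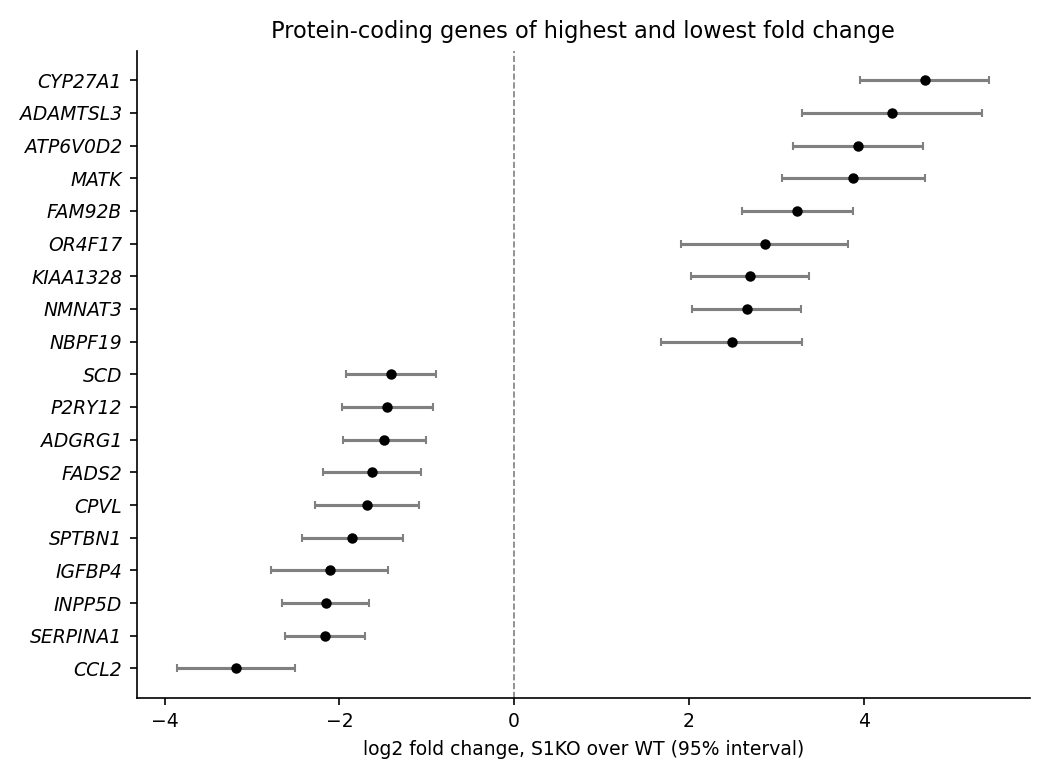
Fitted log2 fold change of S1KO over WT for 9 of the 10 protein-coding genes of highest and the 10 of lowest fold change among those past the threshold, with 95% intervals as bars; the dashed line marks no change. CYP27A1 was highest at 4.70 and CCL2 lowest at -3.18.

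Of 15389 genes tested, 145 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test: 122 were higher and 23 lower in S1KO, and 35 of the higher ones were pseudogenes. This split depended on the scaling. On log2(TPM + 1), which divides by a total that includes the mitochondrial transcripts, limma called 133 higher and 2763 lower, a share of 4.6% higher in place of 84.1%, because the median over all tested genes moved from -0.015 to -0.783; with mitochondrial genes left out of the TPM total, an alternative chosen after the data were seen, it called 270 higher and 28 lower. Fold changes are therefore given relative to TMM scaling, in which the typical gene does not move. The count was fragile: it was 0 without S1KO 1 (1170 genes at an unadjusted p under 0.05) and 0 without S1KO 2 (1641 at an unadjusted p under 0.05), 1973 without WT 1, 2135 without WT 2, and 1160 with DESeq2 on all 4 libraries.

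The identity of the cells was examined through a panel of microglia, complement and pluripotency genes. Transcripts of myeloid and microglial genes were present in all 4 libraries: CSF1R, the receptor that microglia need for survival, stood at 716.1 and 860.4 CPM in WT and 443.1 and 511.9 in S1KO, and SPI1, the myeloid transcription factor PU.1, at 690.1 and 1050 against 699.3 and 685.2. AIF1 (log2 fold change 0.14 ± 0.19 SE) and GPR34 (0.05 ± 0.27 SE) lay within the error of no change, and their sign turned under TPM scaling. TMEM119 was low in every library, between 0.80 and 3.10 CPM. The pluripotency factors POU5F1 and NANOG were low in every library, between 0.71 and 4.80 CPM. Both were higher in both S1KO libraries than in both WT libraries, and neither passed the threshold in edgeR. POU5F1 was at 1.02 ± 0.54 SE (adjusted p = 0.355) and NANOG at 0.94 ± 0.38 SE (adjusted p = 0.252). On log2(TPM + 1) they were at 0.027 and 0.009. P2RY12 alone of the 16 panel genes passed the threshold (-1.45 ± 0.22 SE, adjusted p = 0.0485), and it passed in 10 of its 17 alternatives. TREM2, a lipid-sensing receptor (-1.21 ± 0.22 SE, adjusted p = 0.069), CX3CR1, the fractalkine receptor (-1.04 ± 0.34 SE, adjusted p = 0.185), CSF1R (-0.72 ± 0.21 SE, adjusted p = 0.15) and PTPRC (-0.74 ± 0.21 SE, adjusted p = 0.147) did not pass. CX3CR1 differed within WT, at 149.8 and 70.3 CPM against 50.2 and 56.6 in S1KO. Its log2 fold change ran from -1.82 to -0.395 over the alternatives. DESeq2 called 8 of the 16 and limma on log2(TPM + 1) called 9.

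**Figure D4:**
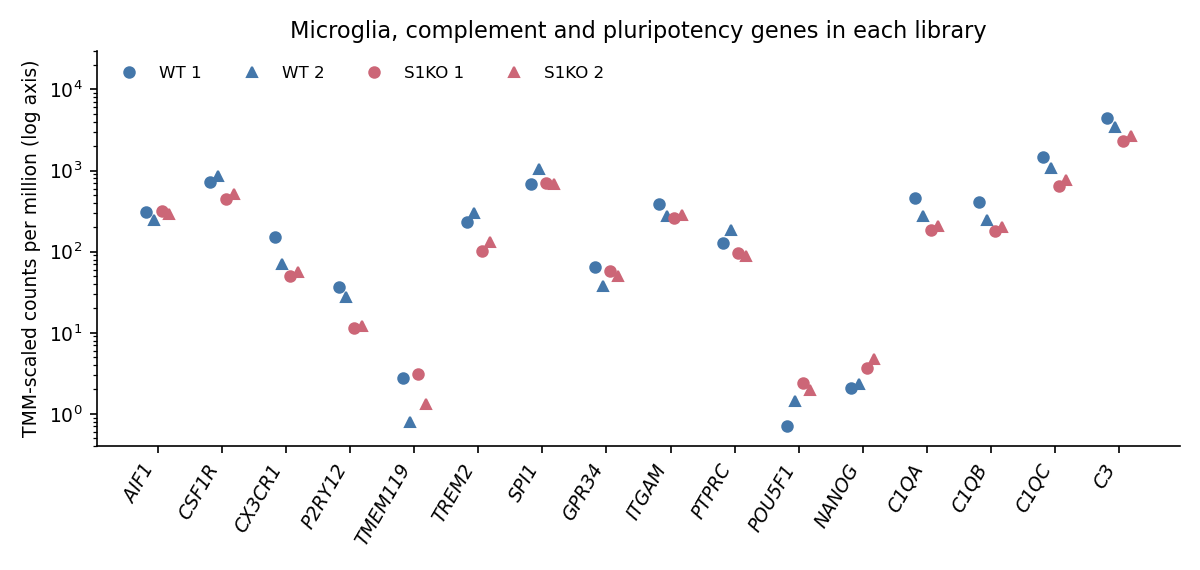
TMM-scaled CPM (log axis) of the 16 panel genes in each library; blue marks WT, red S1KO, circles replicate 1 and triangles replicate 2. P2RY12 was at 36.6 and 27.8 in WT and 11.5 and 12.1 in S1KO, and POU5F1 and NANOG were below 5 in each library.

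As a group, the microglia identity genes were shifted down in S1KO. Of the 28 measured, 20 had a negative fold change, with a median log2 fold change of -0.55, and 18 were lower in both S1KO libraries than in both WT libraries. A random order of the libraries gives 16.7%, but the share over all tested genes is not given here. In the lysosome list, which was not called, 18 of 35 were lower in both S1KO libraries. P2RY12 alone fell among all genes tested (11 members with DESeq2), and adjusted over the list alone 5 genes fell: P2RY12, TREM2, P2RY13 (-0.85), FCGR1A (-1.45) and TGFBR1 (-0.68), the last of these named after its value was seen, and past the threshold over all genes in 3 of 17 alternatives (-0.32 with the effective length offset). The list was called by camera (adjusted p = 0.00241), and not with an estimated correlation (adjusted p = 0.874, p = 0.0545 before adjustment). The estimated correlation was -0.006, below the preset 0.01, so correlation among members did not cause this loss. Both S1KO libraries also held the higher mitochondrial shares, 52.32% and 39.24%.

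The title of the series links SHIP1 to synaptic pruning through complement, which made the phagocytic receptors and the complement genes the next comparison. Of 31 phagocytosis and synapse-pruning receptors, 24 had a negative fold change, with a median of -0.35. ADGRG1 fell among all genes tested (8 members with DESeq2), and adjusted over the list alone 6 genes fell, among them TREM2, FCGR1A (an Fc receptor) and MFGE8, a bridge between phagocyte and target (-1.27 ± 0.28 SE, adjusted p = 0.0954 over all genes). The list was called by camera (adjusted p = 0.0284), but not with an estimated correlation (adjusted p = 0.874, p = 0.0862 before adjustment). The estimated correlation was -0.029, below the preset 0.01, so correlation among members did not cause this loss. The call was also lost with protein-coding transcripts only (camera adjusted p = 0.183, median -0.28). It was lost without WT 2 (median -0.32) and without S1KO 2 (median -0.36) as well. As for the microglia identity genes, both S1KO libraries held the higher mitochondrial shares, 52.32% and 39.24%.

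For the complement system, 19 of 30 measured genes had a negative fold change with a median of -0.23, none passed the threshold over all genes or adjusted over the list alone in edgeR, and the list was not called (camera adjusted p = 0.201; 0.874 as adjusted p with an estimated correlation). DESeq2 on the same libraries called 8 members lower, among them C1QA (adjusted p = 0.0196), C1QC (0.00455), C3 (0.0212) and CD46 (0.00384), and edgeR with no filter called 6. The median was -0.27 without WT 1, -0.08 without WT 2, -0.21 without S1KO 1 and -0.35 without S1KO 2. The C1q chains were lower in both S1KO libraries: C1QA had 454.3 and 275.6 CPM in WT and 184.0 and 209.8 in S1KO (log2 fold change -0.89 ± 0.27 SE, adjusted p = 0.159), C1QB had a log2 fold change of -0.78 ± 0.27 SE (adjusted p = 0.203) and C1QC of -0.85 ± 0.25 SE (adjusted p = 0.15). C1QB had 410.0 CPM in WT 1 and 243.4 in WT 2. Over the alternatives C1QA ran from -1.84 to -0.48, C1QB from -1.70 to -0.35 and C1QC from -1.82 to -0.61. C3, the central complement protein, had 4509 and 3434 CPM in WT and 2327 and 2635 in S1KO (-0.68 ± 0.28 SE, adjusted p = 0.254). The members of smallest p were the complement regulator CD46 (-0.83 ± 0.18 SE, adjusted p = 0.0933), CD93 (-1.87 ± 0.42 SE, adjusted p = 0.0954), the C3a receptor gene C3AR1 (-0.68 ± 0.17 SE, adjusted p = 0.109) and the regulator CD59 (-0.55 ± 0.15 SE, adjusted p = 0.136). With the effective length offset CD59 was at -0.33 and C3 at -0.41, while CD46 (-0.89), CD93 (-1.85) and C3AR1 (-0.675) kept their size. Under a stricter expression filter the list was called down (adjusted p = 0.0424), as it was with protein-coding transcripts only (adjusted p = 0.00928), an alternative chosen after the data were seen.

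**Figure D5:**
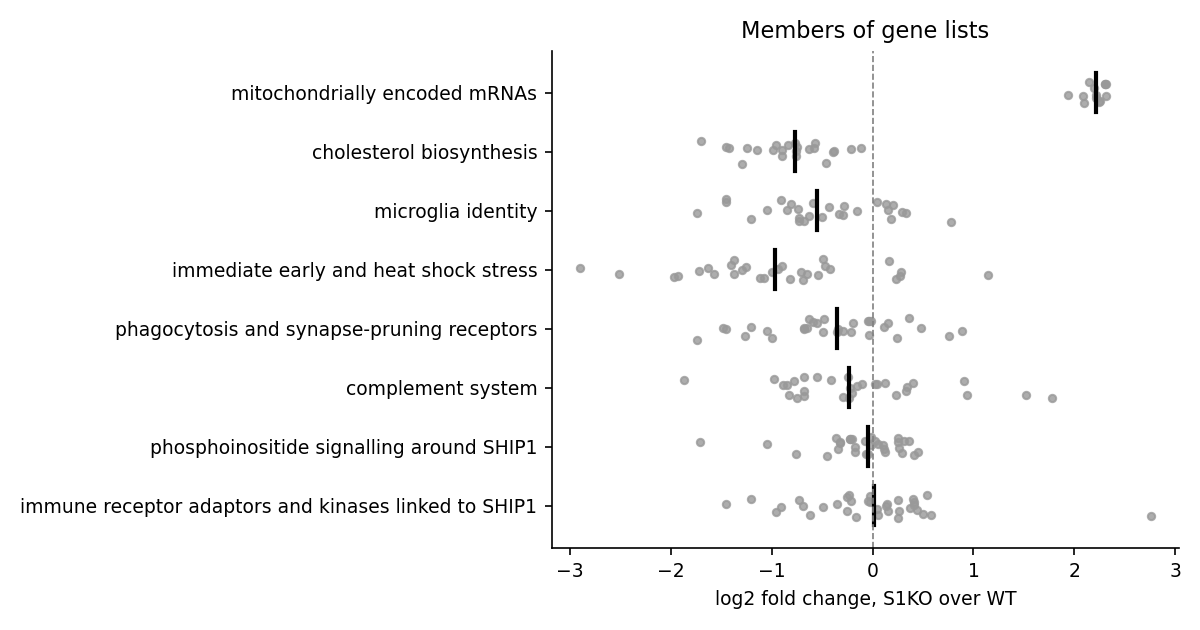
Log2 fold change of S1KO over WT for each measured member of 8 gene lists (grey points, spread vertically for legibility) with the list's median as a black bar; the dashed line marks no change. The upper 5 lists were called by camera with its preset correlation and none with an estimated one, and medians ran from -0.96 for the immediate early and heat shock list to 2.22 for the mitochondrially encoded mRNAs.

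Cholesterol biosynthesis genes were lower in S1KO as a list, by an amount that depended on the WT library. All 23 measured members had a negative fold change, with a median of -0.77, and 18 were lower in both S1KO libraries than in both WT libraries. None passed the threshold over all genes (11 fell with DESeq2), and 14 fell when adjusted over the list alone, including the sterol-sensing regulator INSIG1 (-1.70 ± 0.31 SE, adjusted p = 0.0687 over all genes), CYP51A1 (-1.29 ± 0.25 SE, adjusted p = 0.0824) and LSS (-0.89 ± 0.18 SE, adjusted p = 0.0833). Camera called the list (adjusted p = 1.76e-07), but not with an estimated correlation (adjusted p = 0.874, p = 0.234 before adjustment). The estimated correlation was 0.587, above the preset value, so correlation among members may have caused this loss. Within WT, 21 of the 23 were highest in WT 1, the library that also held mesenchymal transcripts, and the median was -0.49 without WT 1 and -1.04 without WT 2. Here too both S1KO libraries held the higher mitochondrial shares, 52.32% and 39.24%.

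The 13 mitochondrially encoded mRNAs were each higher in both S1KO libraries, with a median log2 fold change of 2.22. None passed the threshold over all genes in edgeR, all 13 did with DESeq2 and in edgeR with no filter, and 12 did without either WT library; the median was 1.18 on log2(TPM + 1), whose total includes these mRNAs. All 13 rose when adjusted over the list alone, and camera called the list up (adjusted p = 6.5e-09). With an estimated correlation the list was not called (camera adjusted p = 0.874). The estimated correlation was 0.982, above the preset value, so correlation among members may have caused this loss. MT-ND3, a complex I subunit, had 1682 and 2355 CPM in WT and 12820 and 5658 in S1KO (2.20 ± 0.47 SE, adjusted p = 0.0933). MT-ND4L (1.93 ± 0.41 SE, adjusted p = 0.0915), MT-ATP8 (2.10 ± 0.45 SE, adjusted p = 0.0933) and MT-ND6 (2.31 ± 0.49 SE, adjusted p = 0.0931) were similar. MT-ND6 lies on the opposite strand to the others and whether the libraries keep strand is not given in the sources used here, so its reads cannot be told from antisense RNA. The S1KO libraries differed from each other by a median of 1.01 on the log2 scale over these genes.

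The list of immediate early and heat shock genes was lower in S1KO, a difference that rested on 1 WT library, WT 2. None of its 6 heat shock genes was highest in WT 2. Of 30 measured genes, 25 had a negative fold change with a median of -0.96, none passed over all genes (4 fell and 1 rose with DESeq2), and JUN alone fell when adjusted over the list alone (-1.29 ± 0.23 SE, adjusted p = 0.064 over all genes). The next members by p were IER3 (-1.37 ± 0.31 SE, adjusted p = 0.0954), the chaperone gene HSPA8, which lay the other way (1.14 ± 0.29 SE, adjusted p = 0.115), and KLF2 (-1.63 ± 0.43 SE, adjusted p = 0.124). HSPA8 kept its sign in 15 of 17 alternatives and was at -0.082 on log2(TPM + 1). Camera called the list down (adjusted p = 0.0144, against 0.874 with an estimated correlation). The estimated correlation was 0.241, above the preset 0.01. Of the 30 genes, 23 were highest in WT 2, and without WT 2 the call was lost and the median was 0.00. The call was also lost without S1KO 2 (0.184) and with protein-coding transcripts only (0.0543), where the medians kept their size (-1.16 and -0.95).

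The signalling genes closest to SHIP1 were not called as groups, and in edgeR 1 receptor among them passed the threshold. Of 31 phosphoinositide signalling genes, 13 had a positive and 18 a negative fold change, with a median of -0.04, and none passed the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.663). Among those of smallest p were SYNJ2, another inositol 5-phosphatase (-0.76 ± 0.31 SE, adjusted p = 0.255), PIK3CB (0.45 ± 0.23 SE, adjusted p = 0.339) and PDPK1 (0.31 ± 0.18 SE, adjusted p = 0.388). PIK3CB and PDPK1 each kept their sign in 15 of 17 alternatives, and were at -0.125 and -0.686 on log2(TPM + 1). Among 34 immune receptor adaptors and kinases, 17 were positive and 17 negative (camera adjusted p = 0.744), and DESeq2 called 1 member higher and 5 lower. LILRB4, an inhibitory receptor, rose (2.75 ± 0.41 SE, adjusted p = 0.0485) from 0.86 and 1.05 to 5.46 and 7.48 CPM, and passed in 9 of its 16 alternatives. With the effective length offset it was at 2.38 ± 0.48 SE (adjusted p = 0.074), a smaller fold with a larger error, and on log2(TPM + 1) at 0.67 ± 0.30 SE (adjusted p = 0.0841). FCER1G, the Fc receptor gamma chain, had a log2 fold change of -0.95 ± 0.16 SE (adjusted p = 0.0595) and passed in 9 of its 17 alternatives. Adjusted over the list alone, 1 gene rose and 3 fell.

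The remaining lists fixed in advance were not called either: camera's adjusted p over the 22 lists without a call ran from 0.104 to 0.85. Disease-associated microglia genes (adjusted p = 0.663) held members that moved apart: LILRB4, whose call was lost with the effective length offset, and GPNMB rose (GPNMB, a lysosomal glycoprotein named after its value was seen, 2.35 ± 0.25 SE, adjusted p = 0.0233, past the threshold in 11 of 17 alternatives and at 1.05 on log2(TPM + 1)), and CCL2 fell. Lysosome genes had a median of -0.22 with a mean of 0.02 (adjusted p = 0.311), and ATP6V0D2 was the member that rose. Alzheimer's disease risk genes (adjusted p = 0.538), glycolysis (0.663), autophagy (0.448), the inflammasome and NF-kB list (0.663) and LXR targets with lipid efflux genes (0.85) were not called. The type I interferon list (0.503), MHC class II presentation (0.104) and the cell cycle (0.234) differed within WT: 26 of 32 interferon genes and all 15 MHC class II genes were highest in WT 2, and 30 of 35 cell cycle genes in WT 1. Their results therefore turned on the WT library: the interferon list was called down without WT 1 (median -1.13) and up without WT 2 (0.54), MHC class II down without WT 1 (-0.98), and the cell cycle down without WT 2 (-0.50). LXR targets were called up without WT 2 (0.67, against -0.27 with all libraries), and the inflammasome list down without WT 1 (-0.26).

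Among markers of other cell types, the mesenchymal genes set 1 library apart. Fibroblast and mesenchymal markers had a median log2 fold change of -4.92 over 9 measured genes (camera adjusted p = 0.311), because 8 of the 9 were highest in WT 1: COL1A1 stood at 2709 CPM in WT 1 against 0.64 in WT 2, 2.56 in S1KO 1 and 11.7 in S1KO 2, and FN1 at 1681 against 2.71, 5.73 and 8.84. This list was called down without WT 2 and up without WT 1, where the endothelial list was called down. The pluripotent stem cell (camera adjusted p = 0.311), haematopoietic progenitor (0.503), monocyte and perivascular macrophage (0.778), lymphocyte (0.575), erythroid and megakaryocyte (0.538), mast cell, granulocyte and dendritic cell (0.663), neural and glial (0.663) and endothelial (0.104) lists were not called. FCN1, a ficolin of the monocyte list named after its value was seen, rose (2.80 ± 0.37 SE, adjusted p = 0.0407) from 1.47 and 1.09 to 9.91 and 7.90 CPM, and passed in 9 of 16 alternatives (0.58 on log2(TPM + 1)). Several members of these lists were well expressed in all 4 libraries, among them STAB1 (3622 to 6642 CPM), ENG (269.5 to 495.9) and CD4 (175.8 to 261.7), all named after their values were seen, so a level alone does not mark another cell type here. Median, mean and test differed in sign for the lysosome, LXR target, receptor adaptor, pluripotent, neural and glial, and mast cell lists.

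The structure of the samples did not follow genotype alone. On the 500 most variable genes the first component held 58.9% of the variance and set WT 1 (score -53.3) apart from WT 2 (4.23), S1KO 2 (18.4) and S1KO 1 (30.6), and the second held 28.9% and set WT 2 (-37.9) apart. The S1KO pair was the closest, with a distance of 79.7 and r = 0.969 across the tested genes. The WT pair (108.8, r = 0.942) lay farther apart than WT 2 and S1KO 2 (103.1, r = 0.947), and genes are not independent replicates.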

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

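Some alternatives were chosen after the data were seen: leaving out mitochondrial genes, using protein-coding transcripts only, and limma on log2(TPM + 1) without mitochondrial genes. The main count of 145 genes became 1160 with DESeq2, 1362 with no filter, 224 with the stricter filter, 304 with robust empirical Bayes, 2896 on log2(TPM + 1), 2642 on log2(TPM + 0.1), 298 on log2(TPM + 1) without mitochondrial genes and 40 with protein-coding genes only. It was 0 at an adjusted p of 0.01 (2993 genes at an unadjusted p under 0.05) and 0 with protein-coding transcripts only (2227 at an unadjusted p under 0.05), all with edgeR, against 1160 with DESeq2 at 0.05. All 145 calls kept their direction and threshold under DESeq2 and no filter, and 69 of 145 on log2(TPM + 1), where 5 had the opposite direction, as did 5 on log2(TPM + 0.1) and 2 with protein-coding transcripts only. Leaving out 1 library gave from 0 (either S1KO library) to 2135 (WT 2), and the S1KO cases estimate the spread with a single S1KO library, hence from the WT pair alone.

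With the replicate number as a block, 0 genes were called by edgeR (2891 at an unadjusted p under 0.05), INPP5D had a log2 fold change of -2.16 at an adjusted p of 0.0501, and 0 panel genes were called. The labels give the numbers no meaning and same-numbered libraries did not deviate together (r = 0.025), so the numbers were not taken as pairs. INPP5D kept its direction in every alternative, with values from -2.70 (log2(TPM + 0.1)) to -1.61 (log2(TPM + 1) without mitochondrial genes). It was at -1.705 with the effective length offset, and its values without 1 library ran from -2.31 to -1.99. Its call was lost with protein-coding transcripts only (-2.32, edgeR adjusted p = 0.0542). The TPM scale put the excess of its retained-intron share at 24.2 percentage points against 9.04 on counts, mainly through the short transcript INPP5D-210.

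The panel count of 1 became 8 with DESeq2, 7 with no filter, 9 on log2(TPM + 1), 8 on log2(TPM + 0.1), 2 with robust empirical Bayes, and 0 with the effective length offset, without mitochondrial genes, with protein-coding transcripts only and on log2(TPM + 1) without mitochondrial genes; without 1 library it ran from 0 to 6. The 5 called lists became 0 with an estimated correlation, 11 on log2(TPM + 1), 3 with protein-coding transcripts only and 0 with fry (17 with fry's test for either direction), and from 3 to 10 without 1 library. The first component held 54.0% of the variance on all tested genes, 56.5% on 2000 genes, 66.8% on log2(TPM + 1) and 56.7% with scaled genes, against 58.9%. Over the other named genes and all their alternatives, 741 values stayed on their side of the threshold, 92 lost it and 153 gained it; none of these named genes changed sign in a called value. Apart from the scaling and the loss of libraries, the cause of these changes was not tested. The lower depth outside mitochondrial genes in S1KO limits what can be said of weakly expressed genes.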

Other observations

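The tests for endoplasmic reticulum chaperones, mitochondrial DNA, genomic DNA, mesenchymal cells and WT 2 were chosen only after results were seen; the fatty acid synthesis and osteoclast lists were prompted by single genes, and the intervals over libraries were set against the bounds after the values were known. Genes outside the naming rule, here XBP1, HSPA5, FASN, DCSTAMP, MMP9, CA2, MCOLN3, ACP5 and OR2M3, were named after their values were seen. XBP1, a transcription factor of the unfolded protein response, fell in S1KO (-1.40 ± 0.19 SE, adjusted p = 0.0432), past the threshold in 11 of 17 alternatives but not with the effective length offset (-1.28 ± 0.22 SE, adjusted p = 0.0511). Of 22 endoplasmic reticulum chaperone genes listed without it, none passed the threshold, and 20 were lower in both S1KO libraries than in both WT libraries, with a median of -0.72. In WT, 18 of the 22 were higher in WT 1, the library with mesenchymal transcripts, than in WT 2, and the median was -0.43 without WT 1. HSPA5, the main chaperone of the compartment, was at 371.3 and 249.6 CPM in WT and 131.6 and 153.4 in S1KO (adjusted p = 0.092). Camera called the list (p = 1.63e-07 adjusted over 3 lists), but not with an estimated correlation (p = 0.152), a weak test with 4 libraries. The list was chosen after results were seen and its median shrank without WT 1. Lower expression of these chaperones therefore stays a hypothesis. Fatty acid synthesis genes other than SCD and FADS2 were the second such group: 16 of 17 had a negative fold change and 12 were lower in both S1KO libraries, with a median of -0.51 (-0.46 without WT 1), 13 were higher in WT 1 than in WT 2, none passed the threshold, and FASN was at -0.98 ± 0.16 SE (adjusted p = 0.0574). Both decreases go with the higher mitochondrial shares of S1KO (52.32% and 39.24% against 14.2% and 18.9% in WT). Camera gave an adjusted p of 7.19e-05 over the 3 lists, and p = 0.0914 with an estimated correlation.

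A set of 3 genes known from osteoclasts was higher in S1KO: ATP6V0D2 (3.93), DCSTAMP, a cell fusion protein (3.12 ± 0.45 SE, adjusted p = 0.046; past the threshold in 13 of 17 alternatives, from 1.89 on log2(TPM + 1) to 3.81 with the effective length offset), and MMP9, a matrix protease (2.16 ± 0.29 SE, adjusted p = 0.0407; in 11 of 17, and at 1.11 with an adjusted p of 0.0779 on log2(TPM + 1)). The hypothesis that an osteoclast-like programme was raised was tested on 19 other osteoclast genes. Of these, 12 were positive and 7 negative with a median of 0.21, and camera did not call them (adjusted p = 0.162), so these data do not carry the idea beyond the 3 genes it came from. CA2 (1.56) and MCOLN3 (1.66) had the smallest p among them, and ACP5 was at 0.85 ± 0.50 SE, none past the threshold.

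The rise of mitochondrially encoded mRNAs was the largest difference between the genotypes in counts. Mitochondrial DNA would add a like amount to each gene, but the rise followed the WT level across the 13 mRNAs (Spearman correlation 0.923), which argues against it. A bias of TPM particular to each gene would scale level and rise alike, so the argument holds only where such bias is small. More mitochondria per cell would bring up the nuclear-encoded respiratory chain genes, and the median of 76 such genes was -0.167 (95% interval over libraries -0.76 to 0.42), below the 0.5 this needed, which argues against it at that size. Loss of cytoplasmic RNA would raise the ratio of retained-intron to coding transcripts; over 5105 genes it moved by a median of -0.303 (-1.27 to 0.67), but it differed as much between the WT libraries (-0.28) and between the S1KO libraries (-0.35), so this test does not decide. Loss of cytoplasmic RNA thus stays open, as does a difference in mitochondrial transcription or RNA stability that goes with the genotype, with the clones, or with the state of the cells at collection, none of which the design separates.

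Olfactory receptor genes, normally silent outside sensory tissue, and repeat-bearing genes were the second pattern. Of 86 olfactory receptor genes with at least 20 counts, 47 were higher and 6 lower in both S1KO libraries. A random order of the libraries gives 14.3 each way, but the share over all tested genes is not given here. The sum over the 86 genes was 839.2 and 892.6 CPM of the counts outside mitochondria in S1KO against 296.5 and 334.4 in WT. The median log2 ratio was 1.004 (95% interval over libraries -0.20 to 2.20), at the bound of 1 set for genomic DNA. This median therefore cannot tell genomic DNA apart from other sources. OR2M3, singled out after its value was seen, took 48.8% of the rise with 2.6% of the length, far more than evenly spread DNA would give it. OR2M3 already held 29.2% and 26.4% of these counts in WT 1 and WT 2, and its share does not speak to the other olfactory receptor genes. Genes whose main transcript holds an Alu repeat lay 0.269 above the others on the log2 scale (0.297 when matched on expression), just short of the bound of 0.3 set beforehand, and 25 of the 87 protein-coding genes that rose held one (28.7%), against 2971 of 14227 tested (20.9%; two-sided Fisher exact test p = 0.0843). The pseudogenes, 35 of the 122 higher calls, and OR4F17 and NBPF19 may belong to this pattern, and a genotype effect on such transcripts remains untested.

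The WT libraries differed from each other more than the S1KO libraries did. In WT 1, 7 of the 9 measured mesenchymal markers were over 8 times higher than in each other library, with COL1A1 at 2709 and FN1 at 1681 CPM, which is consistent with fibroblast-like cells in that culture; the list was fixed beforehand, but the test was chosen after COL1A1 was seen. In WT 2, 23 of 30 immediate early and heat shock genes were highest, with FOS at 1053 and CXCL8 at 199.0 CPM, as were 26 of 32 interferon and 15 of 15 MHC class II genes. None of the 6 heat shock genes was among them, which goes against a heat shock response but leaves open activation of the culture or during collection, or a difference between WT clones. Either way, genes such as CXCL8 (-2.47) and COL1A1 (-7.55) have large fitted fold changes that come from 1 WT library and did not pass the threshold.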
